A study of Homo sapiens with 98 samples.

How the data were processed

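RNA sequencing libraries of sorted T cells from freshly resected primary human tumours were analysed. The sort, called Tconv by the submitters, took conventional CD4+ and CD8+ T cells, while CD25+ CD4+ cells were collected apart as regulatory T cells. Messenger RNA was captured on beads, amplified, and built into libraries with a tagmentation kit. The labels list 98 libraries from 95 tumours of 15 types, and 3 tumours had 2 libraries each.

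The deposited table gives TPM computed by the authors for 19254 gene entries, listed to the hundredth. It holds 349 value columns, of which 95 could be matched to samples of the series, 1 per tumour. The other 254 columns belong to no sample in this series and were not used. For the 3 tumours with 2 libraries (1 bladder tumour, 1 melanoma and 1 pancreatic ductal adenocarcinoma) the table has 1 column each, whose tumour is named here as unnumbered. Every other tumour is named by the replicate number of its library within the type. The submitters' notes name STAR, BWA and the build GRCh38; their versions and roles, the quantifier and the annotation are not given in the sources used here.

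TPM values keep no count of reads, so the depth of each library is unknown, and neither counting intervals nor detection floors could be given. The listed genes summed to between 303824 and 817316 TPM per tumour, with a median of 619259, so the authors' scaling was set over more features than the table lists. Between 4857 and 13055 genes per tumour had a TPM of at least 1, with a median of 10802. No pair of columns was identical, and Pearson's r over genes between 2 tumours ran from 0.4547 to 0.9645, with a median of 0.8163.

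For each tumour, 9 symbols listed more than once were summed and 45 Y-linked genes were left out, which left 19200 genes. Values were analysed as log2(TPM + 1). A gene was tested where its TPM was at least 1 in at least 5 tumours, which kept 15067 genes. Types with at least 5 tumours entered the comparison of types (9 types, 82 tumours), and the other 6 types (13 tumours) are given as values only. limma's linear model with an intensity trend and robust empirical Bayes variances was fitted with type as the factor. An F test asked which genes differed among the 9 types, and each type was then compared with the unweighted mean of the other 8. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and an adjusted p below 0.05 was the threshold. Since each tumour is 1 person's, p-values measure the spread between tumours, not technical error.

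Before the data were examined, 27 gene lists were fixed: exhaustion, cytotoxic effector, effector chemokines, naive and memory stem-like, AP-1 and immediate early, antigen receptor induced, heat shock, tissue residency, proliferation, interferon-stimulated, type 17 and MAIT, T follicular helper, homing receptors, hypoxia and glycolysis, regulatory T cell, NK and gamma-delta T cell, myeloid, neutrophil, B and plasma cell, fibroblast, endothelial, epithelial, melanocyte, hepatocyte, glial, neuroendocrine and erythroid. Of their 219 genes, 216 were in the table. Each list was tested in each type with camera at a preset correlation of 0.01 and again with an estimated correlation. For each list the count of genes past the threshold over all genes stands beside the count adjusted over the list alone. A list score is the mean log2(TPM + 1) of the genes in the list. The 27 scores and 5 further measures of T cell genes (32 measures) were compared between each type and the other tumours in the fit by two-sided permutation tests with 100000 resamples, adjusted over the 288 tests.

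Relations between scores across tumours were given as Pearson's r and Spearman's rho with two-sided permutation p-values (100000 resamples; exact within types of up to 9 tumours), over all 95 tumours and with the mean of each type removed, which leaves out the small intestinal tumour as the sole member of its type. They were adjusted over 16 relations, and within types over 24. The smallest p that these permutations can give is 1e-05. Genes associated with the exhaustion score were found with limma in 88 tumours of 11 types with at least 3 tumours, with type as a factor and the score scaled to its standard deviation of 1.36. The 12 list genes that define the score were left out of the 15129 genes tested.

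Named genes followed a rule fixed at the same time. In each type these were the 5 highest and 5 lowest log2 fold changes outside all lists among genes past the threshold with a log2 fold change of at least 1 in size, and examples of list genes past the threshold. For the exhaustion score they were the 10 highest and 10 lowest slopes, and examples of list genes. CD4, CD8A, CD8B, CD69, PDCD1 and GZMB were always followed. Receptor and immunoglobulin segments, genes with common deletions or unstable mapping, mitochondrial genes and clone-based names were not named. Some genes that met the rule are not reported here, and single-gene alternatives were counted without them.

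Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, quantile normalization, limma array weights, the number of genes detected as a covariate, the mean of the myeloid, B and plasma cell, fibroblast and epithelial scores as a covariate (called the other-cell score), the other tumours pooled as 1 group, each bladder tumour left out in turn, z scores, and CD8A plus CD8B as a covariate for the exhaustion relations. Chosen after seeing the data were rescaling the listed genes to the same total in each tumour, leaving out tumours with fewer than 7500 genes detected, leaving out tumours whose CD3D, CD3E and CD3G summed to under 50 TPM, and CD3 as a covariate. As a further check, the type labels were permuted 99 times with a fixed seed of 11.

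The pipeline was tested on simulated data in which 100 genes were changed by 1 and 100 by 2 on the log2 scale, each up or down at random. Of these it recovered 2 and 38 in 5 bladder tumours, 12 and 76 in 9 melanomas, and 27 and 93 in 16 sarcomas, with 3, 3 and 7 false calls. For the exhaustion slope it recovered 44 of 100 genes at a slope of 0.5 and 98 of 100 at a slope of 1, with 4 false calls. The changed genes were drawn from those with a mean above 2 on the log2 scale. Simulated noise had the spread of the real genes but was independent between genes. Variation shared by many genes of a library was left out, so the false calls do not cover it. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions are from GENCODE on GRCh38. The other sorted fractions of these tumours were not analysed here.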

Results

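Gene expression was measured in conventional T cells sorted from 95 resected human tumours, in a study of whether exhausted CD8 T cells in tumours keep effector function. The tumours comprised 16 sarcomas, 12 gynaecological tumours, 12 hepatobiliary tumours, 9 melanomas, 8 colorectal tumours, 7 glioblastomas, 7 lung tumours, 6 tumours labelled primitive neuroectodermal and 5 bladder tumours. A further 13 tumours belonged to 6 types with at most 3 tumours each. Values are the authors' TPM on a log2 scale after adding 1. The depth of each library is unknown, and the number of genes detected ran from 4857 to 13055.

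The CD3 genes, which encode the invariant chains of the T cell receptor complex, showed how far each library was made of T cell RNA. CD3D, CD3E and CD3G together were under 50 TPM in 8 tumours, with a highest value of 26.3 TPM. In the other 87 tumours they were at least 106.9 TPM, with a median of 884 TPM. The 8 tumours were 2 melanomas, 2 sarcomas, 1 colorectal, 1 gynaecological, 1 gallbladder and 1 primitive neuroectodermal tumour. Fewer than 7500 genes were detected in 9 tumours, among them 3 of the 7 lung tumours and 3 gynaecological tumours.

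**Figure D1:**
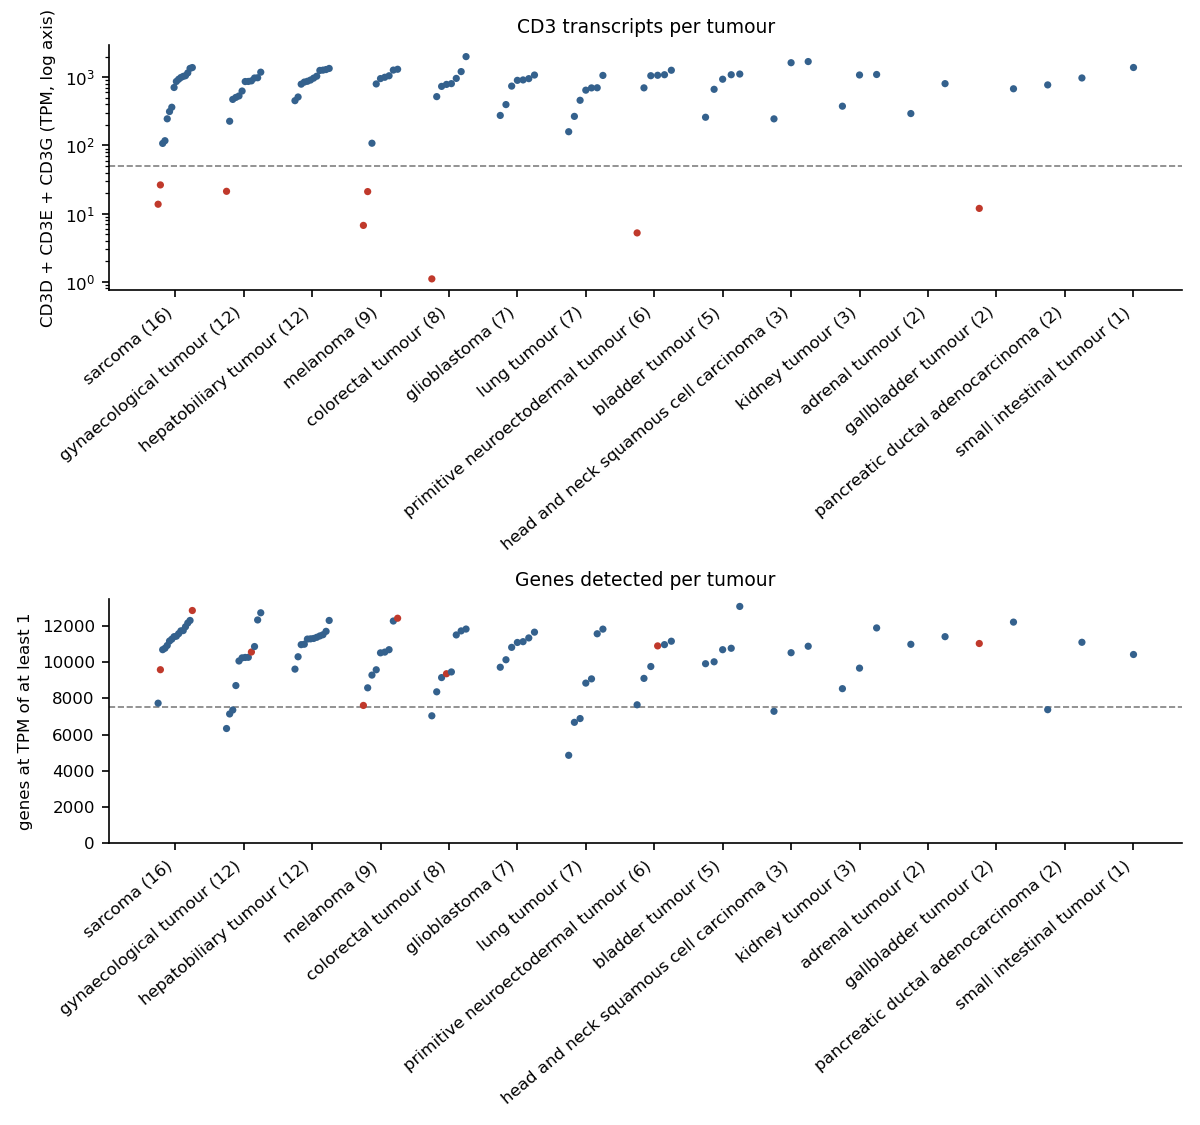
Summed TPM of CD3D, CD3E and CD3G (log axis) and number of genes at a TPM of at least 1, 1 point per tumour, for the 15 tumour types; dashed lines mark 50 TPM and 7500 genes, and red points are tumours under 50 TPM. The 8 red tumours lie at or below 26.3 TPM, and all others at or above 106.9 TPM.

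The first comparison asked whether T cells differed in lineage, residency, exhaustion or killing genes between tumour types. None of the 6 genes followed throughout was shown to differ among the 9 types with at least 5 tumours (82 tumours, limma F test). Sizeable differences are not excluded: CD69 lay 1.76 ± 0.58 (SE, limma adjusted p = 0.12) higher in hepatobiliary tumours. CD8A (chromosome 2, 86784610 to 86808396, minus strand), which encodes a chain of the CD8 co-receptor, averaged 7.18 ± 2.31 (SD, n = 82) with an adjusted p of 0.34. CD8B averaged 4.72 ± 2.07 (SD, adjusted p = 0.4). CD4 (chromosome 12, 6786858 to 6820808), the co-receptor of helper cells, averaged 5.53 ± 1.58 (SD, adjusted p = 0.55). CD69 (chromosome 12, 9752486 to 9760901), a marker of activation and of residency in tissue, averaged 7.32 ± 1.99 (SD, adjusted p = 0.28). PDCD1 (chromosome 2, 241849881 to 241858908), which encodes the inhibitory receptor PD-1, averaged 2.84 ± 1.54 (SD, adjusted p = 0.52). GZMB (chromosome 14, 24630954 to 24634267), the protease granzyme B of killer cells, averaged 6.61 ± 2.37 (SD, adjusted p = 0.67).

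The exhaustion score, built on PDCD1, HAVCR2, LAG3, TIGIT, CTLA4, ENTPD1, TOX, LAYN, CXCL13, BATF, SNX9 and CD200, was not shown to differ between types, and its standard deviation within a type was 0.60 to 1.68. Its mean was 5.21 ± 1.09 (SD, n = 5) in bladder tumours, 4.63 ± 1.38 (SD, n = 8) in colorectal tumours and 4.60 ± 1.61 (SD, n = 16) in sarcomas. It was 4.13 ± 1.68 (SD, n = 9) in melanoma, 4.07 ± 0.84 (SD, n = 12) in hepatobiliary tumours, 3.85 ± 1.15 (SD, n = 7) in lung tumours and 3.82 ± 1.39 (SD, n = 12) in gynaecological tumours. Glioblastoma had 3.77 ± 0.60 (SD, n = 7) and primitive neuroectodermal tumours 3.46 ± 1.09 (SD, n = 6). The largest difference from the other tumours was in bladder tumours, at +1.09 (higher in 5 of 5 tumours, permutation adjusted p = 0.39), so a difference between types was not detectable with these numbers.

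Differences between types were detected in melanocyte, hepatocyte, glial and fibroblast genes, and in heat shock, interferon and innate-like T cell genes. The F test called 1075 of 15067 genes. The count was 394 with quantile normalization, 243 with the number of genes detected as a covariate, and 298 without the tumours under 7500 genes. Of the 243 pairs of type and list, camera called 72 at the preset correlation, and 5 of these held with an estimated correlation. They were melanocyte genes in melanoma, hepatocyte genes in hepatobiliary tumours, glial genes in glioblastoma, fibroblast genes in sarcoma and heat shock genes in bladder tumours. Among the 288 permutation tests of scores, 7 passed. They were these 5 pairs, type 17 and MAIT genes in hepatobiliary tumours, and interferon-stimulated genes in sarcoma. The median log2 fold change of all genes lay between -0.398 (lung) and 0.269 (sarcoma). Quantile normalization moved it by over 0.1 in 7 types: to -0.018 from 0.186 in bladder, -0.019 from -0.243 in colorectal, and -0.002 from 0.131 in glioblastoma. It became -0.036 from -0.139 in gynaecological, -0.006 from 0.254 in hepatobiliary tumours, -0.104 from -0.398 in lung and -0.01 from 0.269 in sarcoma. Rescaling the listed genes moved it to -0.089 in colorectal and 0.148 in hepatobiliary tumours.

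**Figure D2:**
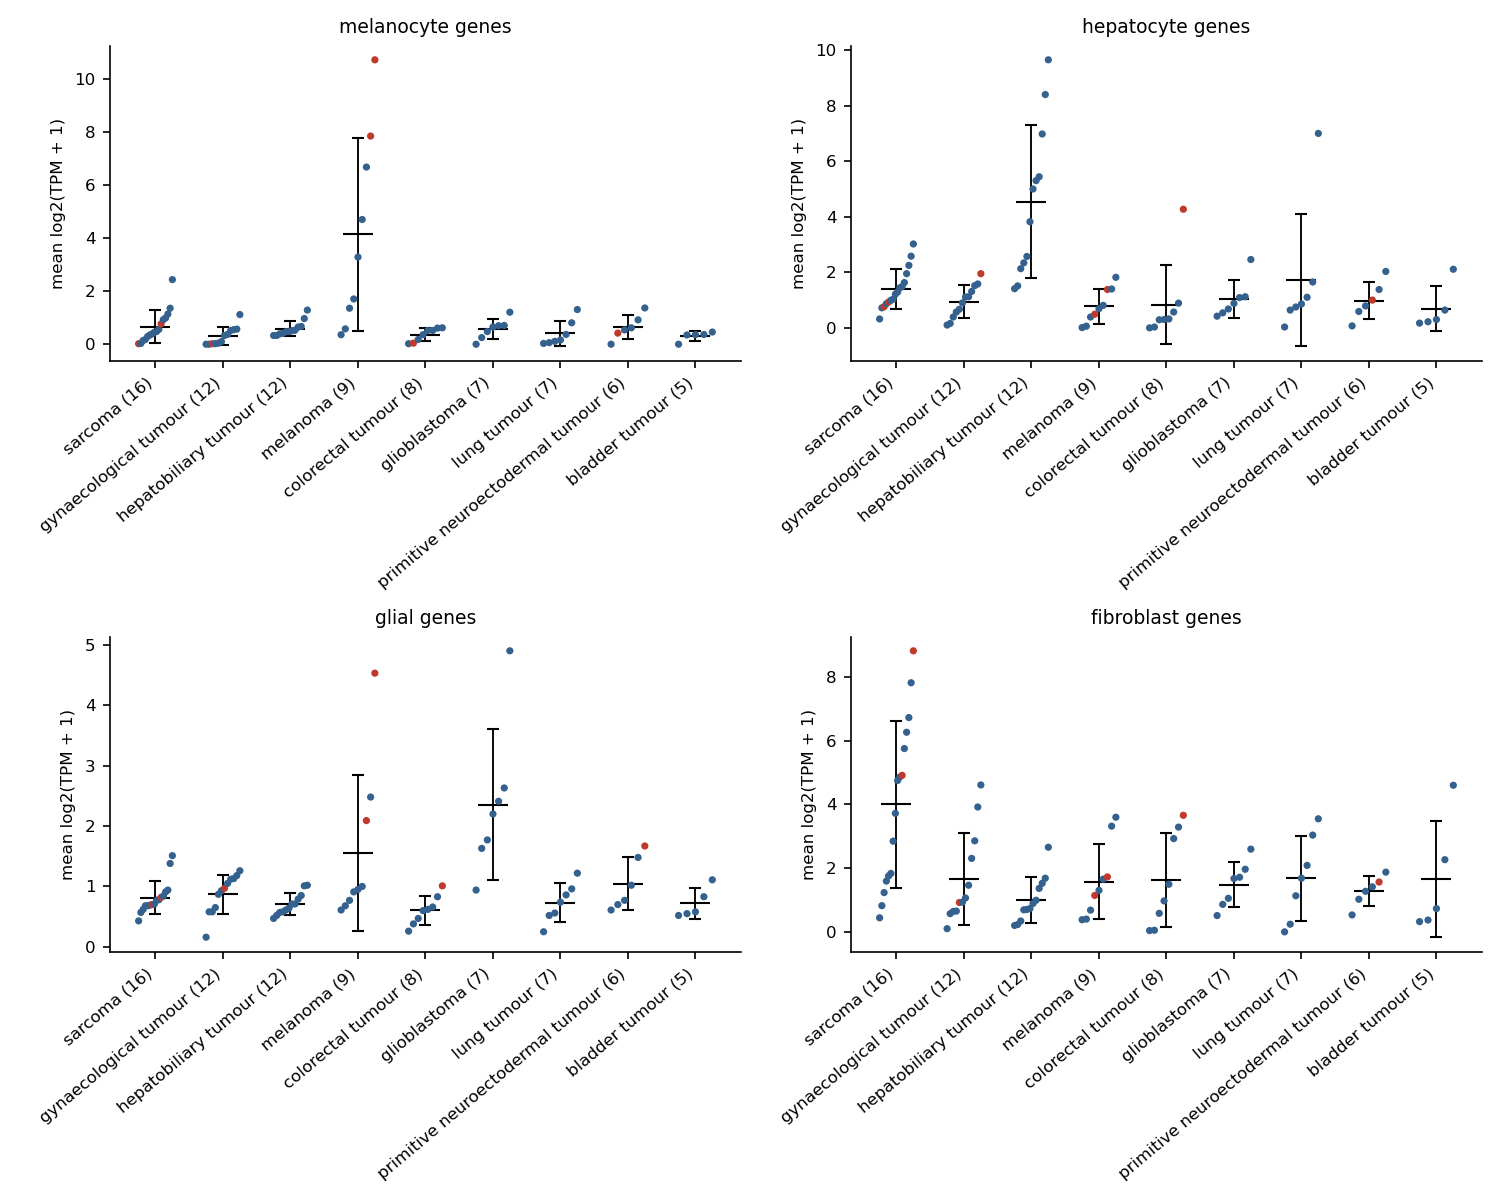
Melanocyte, hepatocyte, glial and fibroblast scores (mean log2(TPM + 1) of the list genes), 1 point per tumour ordered by value within each of 9 types, with bars for mean ± SD; red points are tumours under 50 TPM of CD3. Means in the matching type were 4.14 for melanocyte genes in melanoma, 4.55 for hepatocyte genes in hepatobiliary tumours, 2.35 for glial genes in glioblastoma and 4.01 for fibroblast genes in sarcoma.

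Melanoma libraries had higher melanocyte genes. All 6 melanocyte genes rose (6 over all genes and 6 adjusted over the list alone; median log2 fold change 3.61; camera adjusted p = 1.5e-06 with an estimated correlation). PMEL, a structural protein of the melanosome, rose by 4.68 ± 0.56 (SE, n = 9, limma adjusted p = 1.4e-08). TYR, the enzyme tyrosinase, rose by 3.04 ± 0.39 (SE, adjusted p = 9.7e-08). The melanocyte score was 4.14 ± 3.63 (SD, n = 9) against 0.50 in the 73 other tumours and was higher in 8 of 9 (permutation adjusted p = 0.00096). Outside the lists TFAP2A (3.08 ± 0.42, SE, adjusted p = 4.3e-07) and EDNRB (3.00 ± 0.57, adjusted p = 0.00075) were highest. They were followed by S100A1 (2.54 ± 0.45, adjusted p = 0.00024), the tumour antigen PRAME (2.42 ± 0.57, adjusted p = 0.017) and the melanocyte channel TRPM1 (2.40 ± 0.31, adjusted p = 1.1e-07). One tumour held 85.8% of the group's EDNRB and 1 held 81.3% of its PRAME. Of the genes called, 63 were higher and 4 lower. The lower ones were ATP6V0B (-2.07 ± 0.47, SE, adjusted p = 0.012), B4GALT4 (-1.83 ± 0.47, adjusted p = 0.047), TUBB4B (-1.69 ± 0.42, adjusted p = 0.033) and MYL6 (-1.36 ± 0.33, adjusted p = 0.028).

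T cell effector genes in melanoma lay lower without passing over all genes. Of 12 cytotoxic effector genes 5 were lower adjusted over the list alone and 0 over all genes (limma, 6 at an unadjusted p under 0.05). Their median was -1.44 (camera adjusted p = 5.9e-08, and adjusted p = 0.26 with an estimated correlation). CD8A lay lower as well, without passing (-1.86 ± 0.76, SE, adjusted p = 0.49). Effector chemokines (3 of 6 over the list alone, 0 over all genes, 3 at an unadjusted p under 0.05) had a median of -1.81 (adjusted p = 2.8e-05, and adjusted p = 0.15 with an estimated correlation). Type 17 and MAIT genes (6 of 7 over the list alone, 0 over all genes, 6 at an unadjusted p under 0.05) had a median of -1.23 (adjusted p = 5.9e-06, and adjusted p = 0.14 with an estimated correlation). In the score tests the chemokine difference was -1.77 (higher in 1 of 9 tumours, permutation adjusted p = 0.075). Without the 2 melanomas and the other tumours under 50 TPM of CD3, 14 genes were called in place of 67 and the melanocyte median was 1.91. There MLANA (1.54, adjusted p = 0.29), SOX10 (1.60, adjusted p = 0.069), EDNRB (1.67, adjusted p = 0.3), PRAME (1.27, adjusted p = 0.85) and the 4 lower genes no longer passed. In that setting 3 of the cytotoxic effector genes passed over the list alone, with a median of -1.23. There also 0 of the type 17 and MAIT genes passed over the list alone, although their median stayed at -1.07.

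Hepatobiliary libraries had higher hepatocyte genes, which encode plasma proteins, together with higher innate-like T cell genes. Of 9 hepatocyte genes 7 rose over all genes and 9 adjusted over the list alone (median 3.52; camera adjusted p = 0.00015 with an estimated correlation). ALB, the gene of serum albumin, rose by 4.78 ± 0.51 (SE, n = 12, adjusted p = 1.7e-10). HP, which encodes haptoglobin, rose by 4.28 ± 0.50 (SE, adjusted p = 4.7e-09), and APOA2, which encodes an apolipoprotein, by 5.34 ± 0.66 (SE, adjusted p = 2e-08). The highest genes outside the lists were the secreted liver proteins ORM1 (3.08 ± 0.43, SE, adjusted p = 5e-07), APOC3 (3.01 ± 0.40, adjusted p = 1.5e-07) and AMBP (2.99 ± 0.40, adjusted p = 1.7e-07). RBP4 (2.73 ± 0.53, adjusted p = 0.00062) and the histone gene H3C11 (2.72 ± 0.58, adjusted p = 0.0041) came next. The hepatocyte score was higher in 12 of 12 tumours (4.55 ± 2.74 SD against 1.09, permutation adjusted p = 0.00096).

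Type 17 and MAIT genes, which mark interleukin-17 producing and mucosal-associated invariant T cells, had a score of 3.34 ± 0.86 (SD, n = 12) against 1.99 ± 1.07 (SD, n = 70). It was higher in 11 of 12 hepatobiliary tumours (permutation adjusted p = 0.0043). Of the 7 genes 1 rose over all genes and 5 adjusted over the list alone (median 1.37; camera adjusted p = 0.00039, and adjusted p = 0.26 with an estimated correlation). The gene past the threshold was SLC4A10, a transporter found in MAIT cells (1.83 ± 0.41, SE, adjusted p = 0.0074). Its call ended with quantile normalization (1.40, adjusted p = 0.083) and with genes detected as a covariate (1.58, adjusted p = 0.053). CD40LG, the CD40 ligand of helper T cells (2.28 ± 0.55, SE, adjusted p = 0.014), and CD79B, a chain of the B cell receptor complex (1.31 ± 0.31, SE, adjusted p = 0.011), also rose. Both calls ended with genes detected as a covariate (2.02, adjusted p = 0.088, and 1.07, adjusted p = 0.091). Cytotoxic effector genes had a median of 1.36 with 6 of 12 higher adjusted over the list alone and 0 over all genes (limma, 7 at an unadjusted p under 0.05). Camera gave an adjusted p = 0.0016 (and adjusted p = 0.63 with an estimated correlation). In all 146 genes were called, each higher, while 115 genes were lower at an unadjusted p under 0.05. The count was 72 with quantile normalization (69 higher and 3 lower) and 62 with genes detected as a covariate.

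Glioblastoma libraries had higher glial genes. Of 7 glial genes 2 rose over all genes and 5 adjusted over the list alone (median 2.07; camera adjusted p = 0.00026 with an estimated correlation). GFAP, the intermediate filament of astrocytes, rose by 3.70 ± 0.38 (SE, n = 7, limma adjusted p = 3.1e-11). PTPRZ1, a receptor phosphatase of glia, rose by 2.23 ± 0.47 (SE, adjusted p = 0.014). The glial score was higher in 7 of 7 tumours (2.35 ± 1.26 SD against 0.88, permutation adjusted p = 0.0075). Outside the lists SPP1, which encodes osteopontin (4.74 ± 1.09, SE, adjusted p = 0.045), and the brain metallothionein MT3 (2.39 ± 0.45, adjusted p = 0.0018) were highest among the 13 genes called. Next were the myelin protein PMP2 (2.19 ± 0.23, adjusted p = 3.1e-11), GPM6A (1.94 ± 0.37, adjusted p = 0.003) and IBSP (1.86 ± 0.39, adjusted p = 0.014). None was called lower by limma, with 68 lower at an unadjusted p under 0.05. Epithelial genes had a median of -1.55 (camera adjusted p = 1.5e-09, and adjusted p = 0.14 with an estimated correlation). That of AP-1 and immediate early genes was -0.82 (adjusted p = 4.8e-07, and adjusted p = 0.16 with an estimated correlation), and that of myeloid genes 1.52 (adjusted p = 9e-04, and adjusted p = 0.63 with an estimated correlation).

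Sarcoma libraries had higher extracellular matrix genes and interferon-stimulated genes. Of 8 fibroblast genes 7 rose over all genes and 8 adjusted over the list alone (median 2.59; camera adjusted p = 0.014 with an estimated correlation). The collagen genes COL3A1 (3.55 ± 0.53, SE, n = 16, adjusted p = 1.6e-05) and COL1A2 (3.36 ± 0.58, adjusted p = 0.00015) and the matrix proteoglycan DCN (3.35 ± 0.57, adjusted p = 0.00015) were among them. Highest outside the lists were the matrix protease MMP2 (3.44 ± 0.50, SE, adjusted p = 1.5e-05, TPM of at least 1 in 16 of 16 tumours) and FSTL1 (2.97 ± 0.62, adjusted p = 0.0019). They were followed by the microfibril genes MFAP5 (2.96 ± 0.51, adjusted p = 0.00015) and FBN1 (2.95 ± 0.47, adjusted p = 5e-05), and FOLR2, a folate receptor of macrophages (2.93 ± 0.58, adjusted p = 0.001). The interferon-stimulated score was 4.98 ± 1.42 (SD, n = 16) against 3.64 ± 1.14 (SD, n = 66). It was higher in 13 of 16 (permutation adjusted p = 0.01). Of the 10 interferon-stimulated genes 3 rose over all genes and 10 adjusted over the list alone. Their median was 1.31 (camera adjusted p = 7.9e-07, and adjusted p = 0.17 with an estimated correlation). These 3 were IFI6 (1.71 ± 0.40, SE, adjusted p = 0.0073), IFIT1 (1.74 ± 0.42, adjusted p = 0.0082) and IFIT3 (1.59 ± 0.48, adjusted p = 0.047).

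Proliferation genes in sarcoma had a median of 0.95, with 1 of 9 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00057, and adjusted p = 0.55 with an estimated correlation). The called gene was RRM2, a subunit of ribonucleotide reductase (1.64 ± 0.47, SE, adjusted p = 0.033). Myeloid genes moved with these groups, with a median of 1.89, 1 of 12 higher over all genes and 10 over the list alone (adjusted p = 3e-05, and adjusted p = 0.57 with an estimated correlation). C1QA, a complement gene of macrophages, rose by 1.99 ± 0.54 (SE, adjusted p = 0.025) and the chemokine gene CCL3 by 2.70 ± 0.68 (SE, adjusted p = 0.013). The other-cell score was 3.13 ± 1.21 (SD, n = 16) against 2.07 in the other 66 tumours. With it as a covariate, 6 of the 440 genes called higher in sarcoma remained, and the median of the 440 was 0.81 in place of 1.33. The score includes the fibroblast and myeloid lists, so the lost calls of their genes follow in part from how it is built. CCL3 (1.37, adjusted p = 0.62), C1QA (0.45, adjusted p = 0.8), RRM2 (1.37, adjusted p = 0.48), IFI6 (1.54, adjusted p = 0.17), IFIT1 (1.43, adjusted p = 0.27), and IFIT3 (1.30, adjusted p = 0.53) no longer passed, nor did COL1A2 (1.89, adjusted p = 0.097), DCN (2.08, adjusted p = 0.077), FSTL1 (2.03, adjusted p = 0.23), MFAP5 (2.05, adjusted p = 0.077) and FOLR2 (1.55, adjusted p = 0.3). The count was 92 with quantile normalization and 275 without the tumours under 7500 genes. No gene was called lower by limma, and 51 were lower at an unadjusted p under 0.05.

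Bladder libraries had higher heat shock genes, which encode chaperones induced by stress. The heat shock score was 10.43 ± 1.99 (SD, n = 5) against 7.74 ± 1.64 (SD, n = 77), higher in 4 of 5 tumours (permutation adjusted p = 0.049). All 9 genes were higher adjusted over the list alone and 0 over all genes (limma, 9 at an unadjusted p under 0.05), with a median of 2.88 (camera adjusted p = 0.014 with an estimated correlation). GPR15, a homing receptor that guides T cells to the large intestine, rose by 3.58 ± 0.64 (SE, adjusted p = 0.00061). The neuronal splicing factor gene RBFOX3 (3.49 ± 0.52, SE, adjusted p = 1.2e-05), CCDC194 (3.41 ± 0.70, adjusted p = 0.0061) and DHRS2 (3.04 ± 0.50, adjusted p = 8.9e-05) were highest outside the lists. Next were the squamous cell gene SPRR3 (2.88 ± 0.41, adjusted p = 4.4e-06) and PSCA, a surface antigen of urothelium (2.59 ± 0.35, adjusted p = 2.2e-06). Epithelial genes had a median of 2.01 (5 of 8 over the list alone, 0 over all genes with 5 at an unadjusted p under 0.05; camera adjusted p = 9.1e-08, and adjusted p = 0.17 with an estimated correlation). One tumour held 98.7% of the group's SPRR3 and 1 held 86.7% of its PSCA. Without replicate 5 the SPRR3 value was 1.30, and without replicate 6 the PSCA value was 1.63. CCDC194 lost its call without the unnumbered tumour (adjusted p = 0.17), replicate 3 (0.052), replicate 5 (0.068) or replicate 6 (0.089). The 19 genes called became 29 without replicate 4 and 10 without replicate 6. The heat shock score test no longer passed without the tumours under 50 TPM of CD3 (adjusted p = 0.058) or under 7500 genes (adjusted p = 0.054). In these settings 0 bladder tumours were left out, the median of the list was 3.01 and 2.83, and all 9 genes were higher over the list alone.

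**Figure D3:**
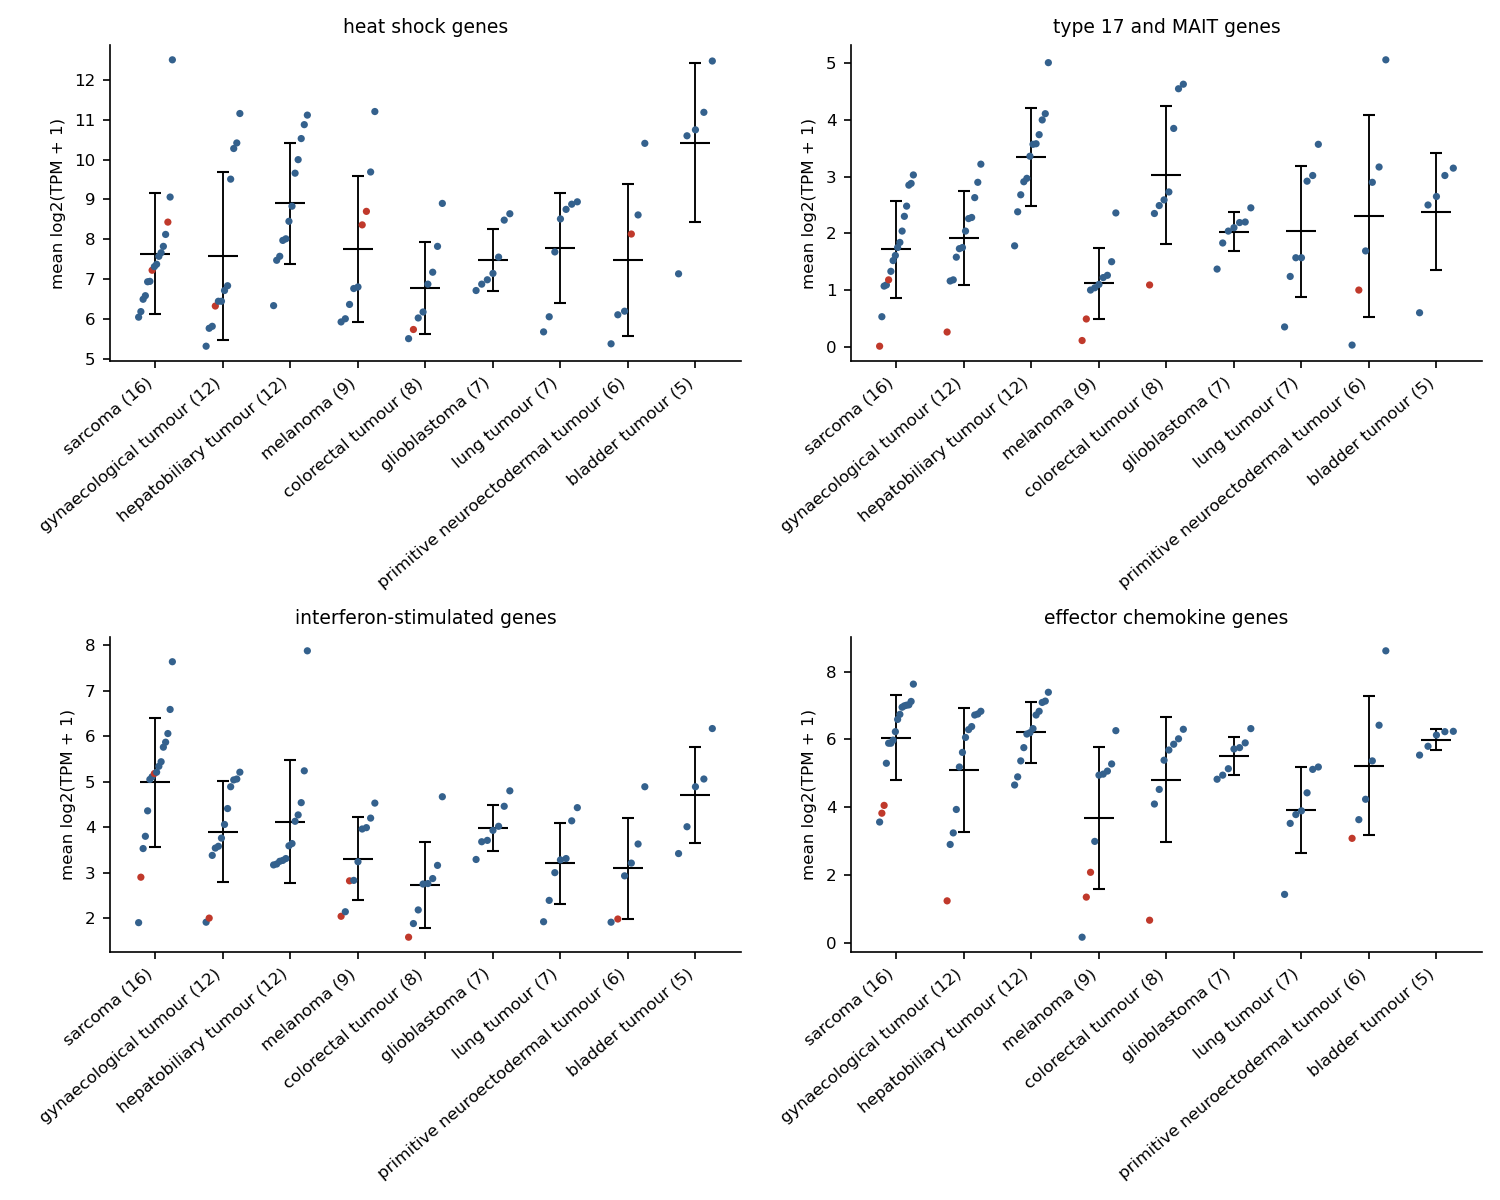
Heat shock, type 17 and MAIT, interferon-stimulated and effector chemokine scores (mean log2(TPM + 1) of the list genes), 1 point per tumour ordered by value within each of 9 types, with bars for mean ± SD; red points are tumours under 50 TPM of CD3. Means were 10.43 for heat shock genes in bladder tumours, 3.34 for type 17 and MAIT genes in hepatobiliary tumours, 4.98 for interferon-stimulated genes in sarcoma and 3.69 for effector chemokines in melanoma.

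In colorectal libraries the gut-homing receptor gene CCR9 (1.96 ± 0.46, SE, n = 8, limma adjusted p = 0.024) and single genes of epithelium were higher. CCR9 lost its call without the tumours under 7500 genes (1.61, adjusted p = 0.12). CEACAM5, the carcinoembryonic antigen, rose by 5.06 ± 0.78 (SE, adjusted p = 7.8e-05, TPM of at least 1 in 7 of 8 tumours). The fatty acid binding protein gene FABP1 rose by 3.43 ± 0.61 (adjusted p = 0.0018) and the tight junction gene CLDN3 by 3.28 ± 0.65 (adjusted p = 0.0053). The mucin gene MUC13 rose by 3.03 ± 0.62 (adjusted p = 0.0074) and GPX2 by 2.98 ± 0.68 (adjusted p = 0.021). Lowest were FCGR3A, an Fc receptor of NK cells and macrophages (-3.67 ± 0.72, SE, adjusted p = 0.0051), and PLEK (-2.47 ± 0.61, adjusted p = 0.04), then ANTXR2 (-2.41 ± 0.47, adjusted p = 0.0051), A2M (-2.30 ± 0.57, adjusted p = 0.041) and DNAJC16 (-2.27 ± 0.47, adjusted p = 0.0089). Of 12 myeloid genes 7 were lower adjusted over the list alone and 0 over all genes (limma, 9 at an unadjusted p under 0.05). Their median was -2.21 (camera adjusted p = 6.6e-06, and adjusted p = 0.55 with an estimated correlation). Type 17 and MAIT genes had a median of 0.89 (2 of 7 over the list alone; adjusted p = 7.5e-07, and adjusted p = 0.092 with an estimated correlation). Interferon-stimulated genes had a median of -1.23 (5 of 10 over the list alone; adjusted p = 0.00035, and adjusted p = 0.45 with an estimated correlation), and epithelial genes 1.65 (5 of 8 over the list alone; adjusted p = 6e-09, and adjusted p = 0.15 with an estimated correlation). The 43 genes called (34 higher, 9 lower) became 76 without the tumours under 50 TPM of CD3, of which 36 were shared. PLEK and A2M lost their calls with quantile normalization (-2.06, adjusted p = 0.12, and -2.06, adjusted p = 0.099).

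In lung libraries most of the genes called were lower, and surfactant genes were higher. TOMM6, of the mitochondrial import pore (-3.42 ± 0.58, SE, n = 7, limma adjusted p = 0.00017), and FUNDC2 (-3.31 ± 0.57, adjusted p = 0.00017) were lowest. They were followed by the respiratory chain gene UQCRQ (-3.28 ± 0.62, adjusted p = 0.00085) and the mitochondrial ribosome genes MRPL58 (-3.27 ± 0.64, adjusted p = 0.0011) and MRPL9 (-3.14 ± 0.58, adjusted p = 0.00058). Among list genes the chemokine CCL3 (-4.37 ± 0.97, SE, adjusted p = 0.003) and the granule protein GNLY (-2.77 ± 0.87, adjusted p = 0.034) fell. So did MAL (-2.46 ± 0.72, adjusted p = 0.023), EGR2 (-2.37 ± 0.73, adjusted p = 0.031) and ISG15 (-2.20 ± 0.73, adjusted p = 0.047). The surfactant genes SFTPA2 (3.19 ± 0.53, SE, adjusted p = 0.00017) and SFTPB (2.94 ± 0.57, adjusted p = 0.001) and the alveolar phosphate transporter SLC34A2 (2.54 ± 0.47, adjusted p = 0.00058) rose, each with a TPM of at least 1 in 3 of 7 tumours. One tumour held 78.9% of the group's SFTPA2 and 1 held 81.1% of its SFTPB. IL5RA (2.72 ± 0.62, adjusted p = 0.004) and LMO3 (2.61 ± 0.40, adjusted p = 2e-05) rose with detection in 5 of 7. Endothelial genes had a median of 0.91 (4 of 6 over the list alone, 0 over all genes with 4 at an unadjusted p under 0.05; camera adjusted p = 5e-05, and adjusted p = 0.17 with an estimated correlation). Of 1172 genes called, 50 were higher and 1122 lower. With quantile normalization 457 were called, 130 higher and 327 lower. Without the tumours under 7500 genes, which leaves 4 lung tumours, 62 genes were called (47 higher, 15 lower). There CCL3 (-3.30, adjusted p = 0.24), GNLY (-2.27, adjusted p = 0.46), MAL (-1.79, adjusted p = 0.46), EGR2 (-1.51, adjusted p = 0.53), and ISG15 (-2.06, adjusted p = 0.37) no longer passed, nor did FUNDC2 (-2.57, adjusted p = 0.06), UQCRQ (-2.49, adjusted p = 0.089), MRPL58 (-2.40, adjusted p = 0.14), MRPL9 (-2.20, adjusted p = 0.11) and IL5RA (1.82, adjusted p = 0.31).

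The fewest genes differed in gynaecological and primitive neuroectodermal tumours. In gynaecological tumours 5 genes were called. Among them the epithelial secreted protein gene WFDC2 (3.58 ± 0.69, SE, n = 12, adjusted p = 0.024) and the kallikrein KLK11 (1.90 ± 0.40, adjusted p = 0.03) were higher. So was the homeobox gene DLX6 (1.34 ± 0.28, adjusted p = 0.026), while OGFOD1 (-1.86 ± 0.39, adjusted p = 0.026) was lower. Epithelial genes as a list had a median of 0.67 (camera adjusted p = 5.4e-05, and adjusted p = 0.39 with an estimated correlation). None of these genes was called without the tumours under 7500 genes (WFDC2 3.09, adjusted p = 0.19; KLK11 1.87, adjusted p = 0.12; DLX6 1.07, adjusted p = 0.077; OGFOD1 -1.49, adjusted p = 0.36). In primitive neuroectodermal tumours VXN (1.98 ± 0.41, SE, n = 6, limma adjusted p = 0.025), the lymphatic growth factor receptor gene FLT4 (1.94 ± 0.40, adjusted p = 0.025) and the exchange factor genes ARHGEF4 (1.87 ± 0.36, adjusted p = 0.022) and DOCK3 (1.37 ± 0.28, adjusted p = 0.025) were higher. One tumour held 89.7% of the ARHGEF4 transcripts of the group. Proliferation genes had a median of -1.15 (adjusted p = 0.00057, and adjusted p = 0.55 with an estimated correlation) and neuroendocrine genes 0.78 (adjusted p = 0.00075, and adjusted p = 0.55 with an estimated correlation). The neuroendocrine score was 5.65 in tumour 3, which was under 50 TPM of CD3, and 0.02 to 1.66 in the others. PNET, the short form in the labels, is also used for pancreatic neuroendocrine tumours, so what these genes mean here is open. With a pseudocount of 0.1 limma called 0 genes in place of 4, with 831 at an unadjusted p under 0.05. Without the tumours under 50 TPM of CD3 VXN (1.5, adjusted p = 0.32) and FLT4 (1.88, adjusted p = 0.11) did not pass.

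T follicular helper, hypoxia and glycolysis, NK and gamma-delta T cell, neutrophil, erythroid, and B and plasma cell genes were called in no type by camera at the preset correlation. Their lowest adjusted p-values were 0.074, 0.056, 0.071, 0.058, 0.099 and 0.05. Homing receptors had a median of -0.98 in melanoma (camera adjusted p = 0.0031, and adjusted p = 0.34 with an estimated correlation). NK and gamma-delta T cell genes had 3 of 5 higher adjusted over the list alone in hepatobiliary tumours (median 0.95, camera adjusted p = 0.071) and 0 over all genes (limma; 3 at an unadjusted p under 0.05). Naive and memory stem-like genes had a median of -0.76 in sarcoma (adjusted p = 3.1e-07, and adjusted p = 0.17 with an estimated correlation), and tissue residency genes -1.14 in melanoma (adjusted p = 0.0031, and adjusted p = 0.37 with an estimated correlation). Antigen receptor induced genes had a median of -0.88 in gynaecological tumours (adjusted p = 0.031, and adjusted p = 0.55 with an estimated correlation). In bladder tumours regulatory T cell genes had a median of 1.37 (adjusted p = 0.0018, and adjusted p = 0.37 with an estimated correlation), and exhaustion genes 1.06 (adjusted p = 0.00098, and adjusted p = 0.55 with an estimated correlation).

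The second comparison addressed the study's title: whether exhaustion and effector genes are found together. Across 95 tumours the exhaustion score (4.17 ± 1.35 SD, from 0.87 to 6.89) and the cytotoxic effector score (5.67 ± 1.70 SD, from 0.55 to 8.25), built on genes such as GZMB, PRF1, GNLY and IFNG, rose together. Pearson's r was 0.585 (permutation p = 1e-05, the smallest they can give; adjusted p = 2.3e-05) and Spearman's rho 0.451 (permutation p = 1e-05). With the type means removed r was 0.649 (permutation p = 1e-05, n = 94) and rho 0.522 (permutation p = 2e-05). Without the 2 tumours farthest from the median exhaustion score r was 0.550 pooled. With type removed it was 0.583 without the 2 tumours farthest in the exhaustion score after its type means were removed. With type and the summed CD8 genes removed r was 0.219 (permutation p = 0.06), and with type and CD3 removed 0.132 (permutation p = 0.25). With type, CD8 and CD3 removed it was -0.002 (permutation p = 0.98). Without the 8 tumours under 50 TPM of CD3 r was 0.334 pooled (permutation p = 0.0015, n = 87) and 0.400 with type removed (permutation p = 0.003, n = 85).

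Within types the relation held in some and not in others. It was found in sarcoma (r = 0.77, rho = 0.72, permutation p = 0.00045, adjusted p = 0.0036, n = 16), colorectal tumours (r = 0.95, rho = 0.83, exact permutation p = 0.0031, adjusted p = 0.019, n = 8) and melanoma (r = 0.84, rho = 0.83, exact permutation p = 0.0097, adjusted p = 0.033, n = 9). Without the 2 tumours farthest from the median exhaustion score r was 0.69, 0.66 and 0.71 in these types. Without their 2, 1 and 2 tumours under 50 TPM of CD3 it was 0.67, 0.8 and 0.71. It did not pass in gynaecological tumours (r = 0.58, permutation p = 0.053, n = 12; r = 0.06 without the 2 farthest) or primitive neuroectodermal tumours (r = 0.56, rho = -0.09, exact permutation p = 0.3, n = 6; r = -0.97 without the 2 farthest). Without the 1 tumour under 50 TPM of CD3 in each of these types, r was 0.03 in gynaecological and -0.93 in primitive neuroectodermal tumours. Nor did it pass in glioblastoma (r = 0.08, exact permutation p = 0.88, n = 7; r = -0.12 without the 2 farthest), lung tumours (r = -0.17, exact permutation p = 0.72, n = 7; r = 0.93 without the 2 farthest) or hepatobiliary tumours (r = -0.48, permutation p = 0.12, n = 12; rho = -0.73, permutation p = 0.01; r = -0.73 without the 2 farthest). The slopes differed between the 8 types in a permutation test of the interaction (F = 2.74, p = 0.014, 77 tumours), and also without the tumours under 50 TPM of CD3 (F = 2.94, p = 0.016, 7 types, 65 tumours). Glioblastoma, lung and hepatobiliary tumours had 0 tumours under that limit. CD3 and CD8 were not removed within single types, so how far T cell content makes these differences was not tested.

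**Figure D4:**
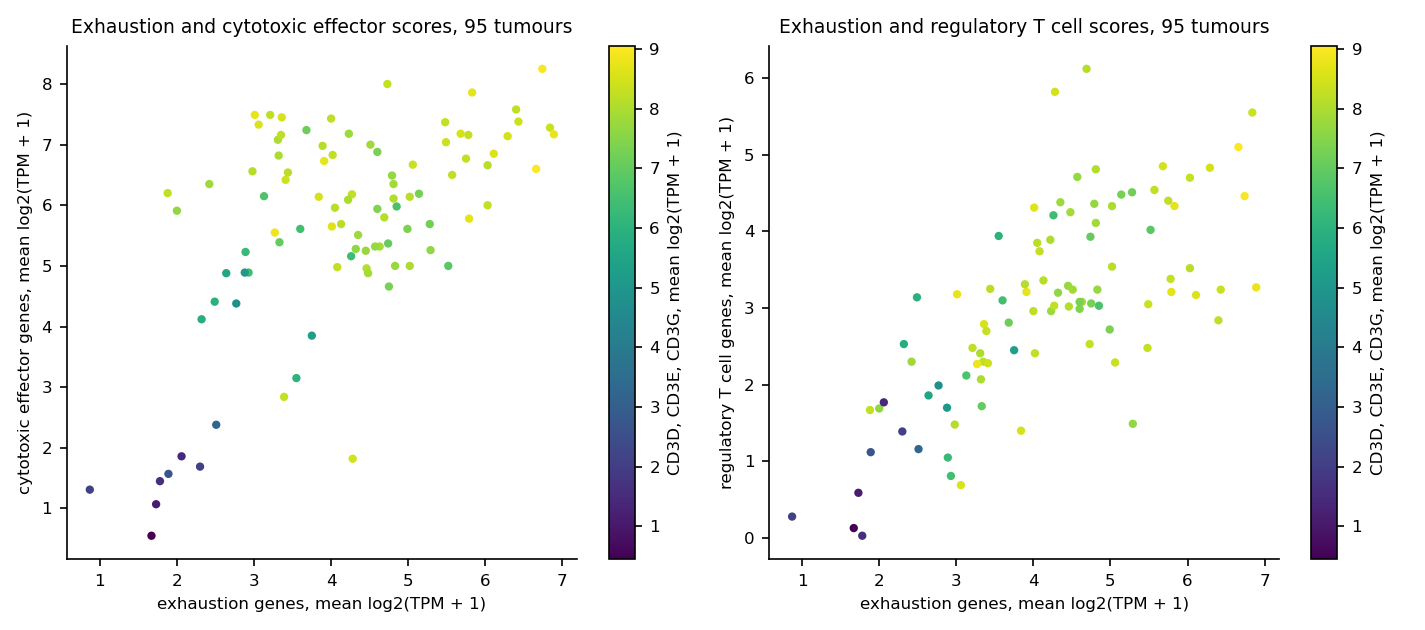
Cytotoxic effector score (left) and regulatory T cell score (right) against the exhaustion score, all on a mean log2(TPM + 1) scale, 1 point per tumour for 95 tumours, coloured by the mean log2 level of the CD3 genes. Pearson's r was 0.585 for the cytotoxic effector score and 0.711 for the regulatory T cell score.

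Regulatory T cell genes such as FOXP3 also rose with exhaustion, although CD25+ CD4+ cells had been sorted apart, with r = 0.711 (rho = 0.714, both permutation p = 1e-05). Each library mixes CD4+ and CD8+ T cells, and which cells held the transcripts of either score was not tested. The exhaustion list holds CTLA4 and TIGIT, which regulatory T cells express as well, so both scores can draw on the same cells. Removing CD8 and CD3 does not take out this overlap. A link with exhaustion of CD8 T cells is therefore not shown by this relation. The r of the regulatory T cell score stayed at 0.697 with type and CD8 removed (permutation p = 1e-05), 0.492 with type and CD3 removed (permutation p = 2e-05) and 0.612 with all 3 removed (permutation p = 1e-05). Within types it was 0.91 in gynaecological tumours (permutation p = 3e-05, adjusted p = 0.00072, n = 12), 0.81 in sarcoma (permutation p = 0.0003, adjusted p = 0.0036, n = 16) and 0.91 in primitive neuroectodermal tumours (exact permutation p = 0.0069, adjusted p = 0.028, n = 6). It did not pass in the other 5 types: glioblastoma (r = 0.75), lung (r = 0.75), colorectal (r = 0.72, rho = 0.05), melanoma (r = 0.44) and hepatobiliary tumours (r = 0.41). Without the 2 farthest tumours r was 0.59, -0.52, -0.03, 0.16 and 0.82 in these types. In colorectal tumours it was -0.24 without the 1 tumour under 50 TPM of CD3. Proliferation genes had r = 0.405 pooled (rho = 0.399; permutation p = 5e-05) and 0.458 with type, CD8 and CD3 removed (permutation p = 2e-05). Within colorectal tumours r was 0.82 (exact permutation p = 0.0045, adjusted p = 0.022, n = 8). The other 7 types did not pass, with r from -0.09 in gynaecological to 0.76 in primitive neuroectodermal tumours. Antigen receptor induced genes had r = 0.495 (rho = 0.441; permutation p = 1e-05) and 0.321 with all 3 removed (permutation p = 0.0043). Tissue residency genes had r = 0.612 (rho = 0.515; permutation p = 1e-05) and 0.213 with all 3 removed (permutation p = 0.082). Effector chemokines had r = 0.471 (rho = 0.357; permutation p = 1e-05) and 0.150 (permutation p = 0.2). Interferon-stimulated genes had r = 0.411 (rho = 0.371; permutation p = 4e-05) and 0.242 with all 3 removed (permutation p = 0.035, adjusted p = 0.093). Naive and memory stem-like genes had 0.321 (rho = 0.208; permutation p = 0.0017), which was -0.224 with type and CD3 removed (permutation p = 0.057). AP-1 and immediate early genes (r = 0.013, permutation p = 0.9), myeloid genes (r = 0.013, permutation p = 0.9) and B and plasma cell genes (r = 0.181, permutation p = 0.079) did not pass. Myeloid genes had r = 0.293 with type, CD8 and CD3 removed (permutation p = 0.0087, adjusted p = 0.028).

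CD69 rose with killing genes and with exhaustion. The 2 relations were not tested against each other. Its r with the cytotoxic effector score was 0.699 (rho = 0.588; permutation p = 1e-05), 0.561 with type and CD8 removed (permutation p = 1e-05), 0.209 with type and CD3 removed (permutation p = 0.066) and 0.342 with type, CD8 and CD3 removed (permutation p = 0.0023). With the exhaustion score r was 0.418 (rho = 0.241; permutation p = 2e-05), 0.263 with type and CD8 removed (permutation p = 0.024), -0.032 with type and CD3 removed (permutation p = 0.78) and -0.013 with all 3 removed (permutation p = 0.91). CD69 and antigen receptor induced genes had r = 0.371 (rho = 0.271; permutation p = 0.00019), and 0.187 with type, CD8 and CD3 removed (permutation p = 0.083). The cytotoxic effector score had 0.448 with antigen receptor induced genes (rho = 0.406; permutation p = 1e-05), which was 0.214 with all 3 removed (permutation p = 0.061), and 0.097 with AP-1 genes (permutation p = 0.35). Of the 15 relations beside that of exhaustion and killing genes, 11 passed pooled.

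The third comparison asked which single genes followed the exhaustion score within types (88 tumours, 11 types). T cell and killing genes rose with it, as did regulatory T cell genes. Per standard deviation of the score, CD3D rose by 1.68 ± 0.17 (SE, adjusted p = 1.4e-12) and CD8A by 1.46 ± 0.19 (adjusted p = 3.6e-09). The granule genes GZMA rose by 1.51 ± 0.19 (adjusted p = 2.9e-09), NKG7 by 1.49 ± 0.20 (adjusted p = 2.6e-08) and GZMK by 1.45 ± 0.19 (adjusted p = 5.4e-09). SIRPG (1.49 ± 0.15, adjusted p = 1.4e-12) and TNFSF4, which encodes OX40 ligand (1.49 ± 0.17, adjusted p = 2.8e-10), also rose. The chemokine CCL5 (1.43 ± 0.17, adjusted p = 1e-09), NELL2 (1.43 ± 0.19, adjusted p = 1.5e-08) and the adhesion gene VCAM1 (1.42 ± 0.20, adjusted p = 4e-08) completed the 10 highest. Lowest were the matrix gene MGP (-1.33 ± 0.23, SE, adjusted p = 8.7e-06), PDK4 (-1.12, adjusted p = 0.00016), NREP (-1.04, adjusted p = 5e-04), and ANK2 (-1.0, adjusted p = 3.5e-05). Then came FXYD6 (-0.99, adjusted p = 0.00062), WDFY3 (-0.99, adjusted p = 3.9e-05), DST (-0.98, adjusted p = 6.6e-05), FER (-0.97, adjusted p = 1.2e-05) and ALDH1A1 (-0.95, adjusted p = 0.0017). In all 3645 genes were called, 2757 rising and 888 falling, with a median slope of 0.094 over all genes. With quantile normalization the split was 1507 to 1503, and with genes detected as a covariate 2169 to 1594.

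By list, 11 of 12 cytotoxic effector genes rose with the exhaustion score over all genes and 12 adjusted over the list alone (median slope 1.13; camera adjusted p = 0.042 with an estimated correlation). Among them were PRF1, which encodes perforin (1.11 ± 0.16, SE, adjusted p = 6.4e-08), and GZMB (1.15 ± 0.23, adjusted p = 7.1e-05). All 6 regulatory T cell genes rose over all genes and over the list alone (median 1.02; adjusted p = 0.027 with an estimated correlation). They included FOXP3, the transcription factor of that lineage (1.03 ± 0.19, adjusted p = 2.7e-05), and CCR8 (1.08 ± 0.19, adjusted p = 6.7e-06). Of 6 tissue residency genes 4 rose and 6 over the list alone (median 0.78; adjusted p = 0.033 with an estimated correlation). CXCR6, a chemokine receptor of resident T cells, rose by 1.42 ± 0.15 (adjusted p = 1.1e-11). Of 9 antigen receptor induced genes 4 rose and 1 fell, the same counts as over the list alone (median 0.39; adjusted p = 0.18 with an estimated correlation). TNFRSF9, which encodes an inducible costimulatory receptor, rose by 1.40 ± 0.13 (adjusted p = 2e-13). Of 9 proliferation genes 7 rose, also over the list alone (median 0.49; adjusted p = 0.36 with an estimated correlation), with MKI67 at 0.78 ± 0.17 (adjusted p = 0.00041). All 7 neuroendocrine genes fell, also over the list alone (camera adjusted p = 0.063 with an estimated correlation). Their median slope was -0.58, and -0.087 without the tumours under 50 TPM of CD3. CD8B (1.38 ± 0.18, adjusted p = 5.4e-09) and CD69 (1.04 ± 0.18, adjusted p = 8.3e-06) rose, while CD4 did not pass (0.34 ± 0.17, adjusted p = 0.14).

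Further lists rose in part: 4 of 6 effector chemokines, 3 of 9 naive and memory stem-like genes (4 over the list alone), 5 of 10 interferon-stimulated genes (6 over the list alone) and 3 of 6 T follicular helper genes (5 over the list alone). So did 4 of 7 homing receptors. As lists these passed camera at the preset correlation but not with an estimated one (adjusted p = 0.16, 0.5, 0.36, 0.063 and 0.061 in this order). Hypoxia and glycolysis genes (2 of 11 rising, camera adjusted p = 0.77), type 17 and MAIT genes (1 of 7, 2 over the list alone, camera adjusted p = 0.77) and B and plasma cell genes (1 of 6, camera adjusted p = 0.8) did not pass as lists. Without the tumours under 50 TPM of CD3, 1 effector chemokine, 2 interferon-stimulated genes, 1 T follicular helper gene and 3 homing receptors rose. Of the naive and memory stem-like genes 0 passed there in limma, with 1 at an unadjusted p under 0.05 and a median of -0.11. With CD8 as a covariate 1 interferon-stimulated gene and 2 T follicular helper genes rose. Of the effector chemokines, naive and memory stem-like genes and homing receptors 0 passed in limma with CD8, with 1, 1 and 3 at an unadjusted p under 0.05. Of 10 AP-1 and immediate early genes 1 rose and 2 fell, and of 5 NK and gamma-delta T cell genes 1 rose and 1 fell. In the endothelial, epithelial and glial lists 1 gene each fell, and 1, 0 and 1 over the list alone. Without the tumours under 50 TPM of CD3 0, 0 and 1 fell (limma, 1, 0 and 1 at an unadjusted p under 0.05). Of the heat shock, myeloid, neutrophil, fibroblast, melanocyte, hepatocyte and erythroid genes 0 passed in limma, with 0, 0, 0, 2, 0, 2 and 0 at an unadjusted p under 0.05.

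With CD8A plus CD8B as a covariate 437 genes were called (403 rising, 34 falling), 404 of them shared. Of the lists, 5 of 6 regulatory T cell genes, 4 of 9 proliferation genes and 3 of 9 antigen receptor induced genes still rose. By contrast 0 of 12 cytotoxic effector genes passed in limma, with 3 at an unadjusted p under 0.05. Without the tumours under 50 TPM of CD3 1278 genes were called, 1104 of them shared. In that setting 6 of 12 cytotoxic effector genes, 4 of 6 regulatory T cell genes and 6 of 9 proliferation genes rose. There 0 of the 6 neuroendocrine genes tested passed in limma, with 0 at an unadjusted p under 0.05. With CD8 and CD3 as covariates CCR8 (1.36 ± 0.26, SE, adjusted p = 0.00076), FOXP3 (1.02 ± 0.26, adjusted p = 0.014), and TNFRSF9 (1.30 ± 0.18, adjusted p = 5.8e-07) still rose. So did MKI67 (1.27 ± 0.24, adjusted p = 0.00061), TNFSF4 (1.78 ± 0.24, adjusted p = 4.7e-07), VCAM1 (1.47 ± 0.26, adjusted p = 0.00016) and SIRPG (1.03 ± 0.20, adjusted p = 0.0015). GZMB (0.04 ± 0.27, adjusted p = 0.97), CD8A (-0.01 ± 0.07, adjusted p = 0.98) and CD69 (-0.02 ± 0.20, adjusted p = 0.99) did not. In this fit myeloid genes had a median slope of 0.93, against 0.09 with type alone, and regulatory T cell genes one of 0.86. Of the 12 myeloid genes 0 passed in limma, with 7 at an unadjusted p under 0.05.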

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

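In the 3 patterns weighed here, every test was chosen after the result or a closely related one was seen, except that of whether tissue transcripts vary together within a type, which was set before its result; removing CD8, removing genes detected and the other-cell score as a covariate were alternatives fixed in advance. The tests for a tumour far from the rest of its type followed a fixed rule. How the label permutations were to be read was written down only after results were seen.

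In the 6 types of 4 to 10 tumours, 198 tests looked for a tumour far from the others of its type. They found 37 cases, of which 18 were in tumours under 50 TPM of CD3. Chance gives about 1 case in 20 only where values are normally distributed. Several scores lie near 0 and many cases share a tumour, so the number of cases cannot be set against that rate. All values are on the log2 scale of TPM + 1. Colorectal tumour 4 was lowest in exhaustion (1.67, others 4.35 to 6.11), cytotoxic effector (0.55, others 4.88 to 6.85), effector chemokines (0.68), homing receptors (1.01), regulatory T cell (0.13), CD8A (1.24), CD69 (0.18) and mean CD3 (0.45, others 7.40 to 8.72), and highest in hepatocyte (4.27, others 0.00 to 0.89) and neuroendocrine genes (5.99, others 0.00 to 0.51). Primitive neuroectodermal tumour 3 was lowest in cytotoxic effector (1.07, others 5.32 to 7.33), CD8A (0.54), CD8B (0.16), CD69 (3.07) and mean CD3 (1.10, others 7.70 to 8.58), and highest in epithelial (4.29) and neuroendocrine genes (5.65, others 0.02 to 1.66). Primitive neuroectodermal tumour 4 was lowest in AP-1 and immediate early genes (6.81, others 8.41 to 8.69).

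The unnumbered bladder tumour was highest in antigen receptor induced genes (7.10, others 5.58 to 5.84) and lowest in type 17 and MAIT (0.60, others 2.50 to 3.15) and melanocyte genes (0.00). Bladder tumour 5 was highest in B and plasma cell (1.82), endothelial (1.30) and hepatocyte genes (2.11) and lowest in CD8A (5.57, others 8.11 to 8.76), and bladder tumour 3 was lowest in CD4 (5.14, others 6.41 to 6.65). Colorectal tumour 7 was highest in neutrophil genes (4.86, others 0.04 to 2.08) and colorectal tumour 3 in erythroid genes (2.63). Glioblastoma 4 was highest in glial (4.90, others 0.94 to 2.63), endothelial (1.19) and hepatocyte genes (2.46) and lowest in tissue residency genes (3.85). Lung tumour 3 was highest in hepatocyte (7.00, others 0.03 to 1.65) and NK and gamma-delta T cell genes (3.95), and lung tumour 1 was lowest in AP-1 and immediate early genes (5.07). Melanoma 1 was highest in glial genes (4.53, others 0.61 to 2.48) and melanoma 2 in endothelial genes (2.07). Between types, the slope of the cytotoxic effector score on the exhaustion score differed (permutation p = 0.014).

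Transcripts typical of the surrounding tissue were higher in melanoma, hepatobiliary tumours, glioblastoma and sarcoma. Leaving out the tumours under 50 TPM of CD3 moved the list median from 3.61 to 1.91, 3.52 to 3.56, 2.07 to 2.23 and 2.59 to 2.26. It fell below its halfway mark in 0 of 4 types. Hepatobiliary tumours and glioblastoma had 0 tumours under that limit, so such libraries were not the source of the rise there. The test had force only in melanoma and sarcoma, with 2 tumours left out in each. In melanoma the median came close to its halfway mark, so a large part played by these libraries stays open there. Within the type the list genes varied together in 4 of 4 types (mean pairwise r 0.88, 0.84, 0.70 and 0.85, against 95th percentiles of 0.42, 0.37, 0.24 and 0.31 for random lists). Tumour or stromal RNA that entered each library as 1 source would give this, although the sort should have removed those cells. The random lists were matched on mean level only, so genes of 1 cell type could exceed them whatever their source. The test therefore does not single out this source. Whether tumour or stromal RNA came as free RNA or with cells caught beside T cells was not tested. That T cells themselves differ between tumour types in these genes stays open as untested.

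Most of the genes called in lung tumours were lower, 1122 of 1172. RNA of other cells in the lung libraries stays open: with the other-cell score as a covariate 1385 genes were called, but that score was 2.27 in lung tumours against 2.28 in the others, so its removal could hardly have lowered the count. Few genes detected in 3 of the 7 libraries is a candidate explanation: without the tumours under 7500 genes the median of the 1122 genes was -1.13 (quartiles -1.51 and -0.72) in place of -1.78, while that of all genes was -0.13. In tumours of other types under 7500 genes these genes were also lower than in the rest of their type (-1.08, against -0.68 for all genes). Fewer genes were also called in lung tumours with genes detected as a covariate or with array weights, both fixed in advance (counts in the next section). Since few genes were detected in lung libraries, that covariate also takes out part of any lung difference. The 1122 genes were chosen with the 3 libraries among the 7. Few genes detected and a difference of lung tumours, which was not tested, therefore cannot be told apart.

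The exhaustion and cytotoxic effector scores rose together, at r = 0.649 with type removed. The number of genes detected was argued against, since r was 0.646 with it removed. T cell content of the library may account for the relation, as r was 0.132 (permutation p = 0.25) with type and CD3 removed, and so may the amount of CD8 transcripts, as r was 0.219 (permutation p = 0.06) with type and CD8 removed; CD3, CD8 and killing genes are made by the same cells, so neither removal separates content from cell state. Without the tumours under 50 TPM of CD3 r was 0.400 (permutation p = 0.003). A shared state of exhausted cells that still kill stays open, and no test here told it apart from content alone.

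For the counts of genes by type, 100 labellings of the tumours (99 drawn and the real one) were compared. Chance is an unlikely source of the 1075 genes among all types (1 labelling as large, highest other 10), the 146 in hepatobiliary tumours (1, highest other 22) and the 1172 in lung tumours (1, highest other 295). Few labellings reached the 440 in sarcoma (2, highest other 638) and the 67 in melanoma (4, highest other 729). Chance was not excluded for these, since a drawn labelling called more genes in each. Nor can it be excluded for the 19 in bladder tumours (13, highest other 1064), 43 in colorectal tumours (5, highest other 391), 13 in glioblastoma (7, highest other 80), 5 in gynaecological tumours (9, highest other 758) and 4 in primitive neuroectodermal tumours (22, highest other 132). Melanoma and colorectal tumours lie 1 labelling apart here, and these 10 counts were not adjusted for their number. Drawn groups that call several times the real count may point to a structure among the samples that crosses tumour types, which was not tested against a few extreme libraries falling into 1 drawn group.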

How the results depend on the processing

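Rescaling to listed genes, leaving out tumours under 7500 genes or under 50 TPM of CD3, and CD3 as a covariate were chosen after seeing the data; the other alternatives were fixed in advance. No paired analysis was possible because each tumour belongs to 1 type and each replicate number only names a library within its type. The first library of each tumour alone was not run, since the table does not separate libraries of 1 tumour. Depth is unknown, so limits set by read counts were not examined. The cause was not tested where a count below moved, except that leaving out tumours also lowers n.

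Genes differing among tumour types (1075) were 394 with quantile normalization, 2493 with array weights, 243 with genes detected as covariate, 450 rescaled and 298 without tumours under 7500 genes. Genes differing in bladder tumour (19) were 67 with no filter, 46 with array weights and 10 to 29 with each tumour left out. Genes differing in colorectal tumour (43) were 269 with array weights, 70 with genes detected, 69 with the other-cell score and 76 without tumours low in CD3. Genes differing in glioblastoma (13) were 24 with no filter, 680 with array weights, 40 with the other-cell score and 24 without tumours low in CD3. Genes differing in gynaecological tumour (5) were 8 with a pseudocount of 0.1, 17 with quantile normalization, 12 with genes detected, 2 without tumours under 7500 genes and 1 without tumours low in CD3. Genes differing in hepatobiliary tumour (146) were 72 with quantile normalization, 1648 with array weights, 62 with genes detected and 84 rescaled. Genes differing in lung tumour (1172) were 2301 with a pseudocount of 0.1, 457 with quantile normalization, 51 with array weights, 86 with genes detected, 62 without tumours under 7500 genes and 1951 without tumours low in CD3. Genes differing in melanoma (67) were 43 with a pseudocount of 0.1, 107 with no filter, 104 with quantile normalization, 43 with array weights, 131 with the other-cell score and 14 without tumours low in CD3. Genes differing in primitive neuroectodermal tumour (4) were 0 with a pseudocount of 0.1 (limma; 831 at an unadjusted p under 0.05), 18 with no filter, 18 with quantile normalization, 28 with array weights, 9 with genes detected, 2 rescaled and 8 without tumours low in CD3. Genes differing in sarcoma (440) were 92 with quantile normalization, 1912 with array weights, 112 with genes detected, 6 with the other-cell score, 194 rescaled and 275 without tumours under 7500 genes.

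Genes associated with the exhaustion score (3645) were 437 with CD8, 1478 with array weights, 1278 without tumours low in CD3 and 305 with CD8 and CD3. Of the gene lists by tumour type, 5 in place of 72 were called with an estimated correlation. The exhaustion and cytotoxic effector scores across tumours (0.585) gave 0.219 with type and CD8 removed, 0.132 with type and CD3, and -0.002 with type, CD8 and CD3; the cause was not tested further. The other relations between scores across tumours passed in 3 with type and CD3 removed, 5 with CD8 as well and 7 without tumours low in CD3 with type removed, in place of 11. Exhaustion with naive and memory stem-like reversed to -0.224 and -0.166 in the first pair of settings, and to -0.042 and -0.055 without tumours low in CD3, pooled and with type removed. Exhaustion with CD69 reversed to -0.032 and -0.013.

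Slopes were followed through all settings for the genes named by rule and up to 4 called genes per list. Among them, with CD8 and CD3 as covariates, slopes reversed for CD8A (-0.009), FXYD6 (0.204), XCL2 (-0.093), XCL1 (-0.021), IL7R (-0.253), EGR1 (0.143), KLRB1 (-0.6), ITGB7 (-0.251), KLRC1 (-0.012) and CD69 (-0.016). Other called list genes reversed there too: GNLY (-0.364), IFNG (-0.226), KLRD1 (-0.301), TBX21 (-0.167), SCG5 (0.241) and SYP (0.136). With CD8 alone they reversed for XCL2 (-0.003), KLRB1 (-0.124) and KLRC1 (-0.042), and outside that set for IFNG (-0.058) and KLRD1 (-0.162). They reversed without tumours low in CD3 for IL7R (-0.03), KLRB1 (-0.125) and, outside that set, SCG5 (0.032), and with array weights for KLRB1 (-0.158). In all, of the 802 followed slope values for 73 genes 620 stayed on their side of the threshold, 166 fell short of it and 16 reversed. Of 976 values for 95 pairs of gene and type 829 stayed, 147 fell short and 0 reversed, and of 255 values for 15 relations 226 stayed, 19 fell short, 4 newly passed and 6 reversed.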

Other observations

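The 6 types with at most 3 tumours enter no test and are given as values; the genes named in the second paragraph were chosen after their values were seen. Exhaustion scores were 2.49, 6.66 and 6.74 in 3 head and neck squamous cell carcinomas and 2.42, 4.85 and 5.49 in 3 kidney tumours. They were 3.31 and 3.60 in 2 adrenal tumours, 1.78 and 4.79 in 2 gallbladder tumours, 4.08 and 4.22 in 2 pancreatic ductal adenocarcinomas and 3.27 in the small intestinal tumour. Cytotoxic effector scores were 4.41, 6.60 and 8.25 in the head and neck carcinomas, 5.98, 6.35 and 7.04 in the kidney tumours, 5.61 and 7.08 in the adrenal tumours, 1.45 and 6.49 in the gallbladder tumours, 4.98 and 6.09 in the pancreatic adenocarcinomas and 5.55 in the small intestinal tumour. CD69 was highest in the small intestinal tumour, at 10.93, among these 13 tumours. The balance of CD8 to CD4 transcripts, log2((CD8A + CD8B + 1)/(CD4 + 1)), averaged 1.96 ± 2.55 (SD) over all 95 tumours, from -7.56 to 9.20.

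With CD8 and CD3 as covariates, genes outside the lists with large slopes on the exhaustion score included GEM (1.84 ± 0.21, SE, limma adjusted p = 7.5e-10), MYO7A (1.80 ± 0.16, adjusted p = 7.3e-14) and the phosphatase DUSP4 (1.35 ± 0.19, adjusted p = 7.3e-07), each of which also rose without these covariates (0.82, 1.28 and 1.33). In the other direction were S1PR5, a receptor that guides cells out of tissue (-1.27 ± 0.28, adjusted p = 0.0037), and the transcription factor MYBL1 (-1.27 ± 0.21, adjusted p = 4.7e-05). Without the covariates these had slopes of -0.25 (adjusted p = 0.42) and 0.02 (adjusted p = 0.95).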
